A study of Homo sapiens with 6 samples.

How the data were processed

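Total RNA of Caco-2 cells was extracted with Trizol and labelled with biotin for Affymetrix arrays, per the labels' protocols. The labels give 6 arrays in 2 groups, NC and apoM overexpression, with 3 arrays each and replicate numbers 1 to 3 in each group. The deposited values are on a log2 scale, judged from their range, and were processed in Affymetrix Expression Console, per the submitters' processing notes; its version, the normalization method and the genome build are not given in the sources used here. For this reason no genome coordinates are given. The table held 135750 features per array and was not normalized again. Signal over background was not part of the table, so no feature was called absent, and dim genes were kept.

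Features were named through the platform annotation, in which 36176 features carry 1 gene symbol, 1119 several and 98455 are unnamed here. Of the one-symbol features, 25516 were matched to the GRCh38.p14 gene table by gene ID, 9888 by symbol only and 772 were not matched. No gene was named from a feature with several symbols, and list members measured only on such features, RPS27A among them, were not analysed here. For each gene the feature with the highest mean over the 6 arrays was used, which gave 33616 genes, 1576 of them with more than 1 feature. Gene spans from the same table include introns.

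Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with default settings, apoM overexpression minus NC, two-sided, Benjamini-Hochberg adjustment over all genes, threshold 0.05). Gene lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives; all 41 lists qualified. Older symbols in the lists were matched through synonyms. That step was corrected after the first list results, when a mitochondrial gene had been matched to a pseudogene; 6 lists passed before and after. APOM was also tested by exact permutation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

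The groups, tests, lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule named APOM, RPS27A and VDR, the 12 largest rises and 12 largest falls among protein-coding genes past the threshold whose groups did not overlap, and up to 4 members with the smallest p of each list described. The alternatives fixed beforehand were quantile normalization, subtraction of array medians, genes above the median level, the mean of a gene's features, eBayes with trend and robust, array weights, the replicate number as a block, each array left out, all features, and other thresholds. The restriction to protein-coding genes, the restriction to features with a gene ID and the removal of the gene-span trend (lowess span 0.3) were chosen after seeing the data, as were the classes of RNA and the gene families.

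The procedure was tested on simulated data of 3 against 3 arrays over 33616 genes. It recovered 4% of planted changes of 0.5 on the log2 scale, 64% of changes of 1, and 100% of changes of 2 and 4, with 11 false calls. The 1 list planted was the 1 called. Noise was drawn for each gene on its own. The simulation therefore could not show how often lists pass when genes vary together across arrays.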

Results

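Gene expression was measured on Affymetrix arrays in Caco-2 cells, a human colon carcinoma line that is widely used as a model of the intestinal epithelium. The labels place 3 arrays in a group named NC and 3 in a group that overexpressed apoM. Apolipoprotein M, encoded by APOM, is a carrier of sphingosine-1-phosphate on high-density lipoprotein. The table held log2 values of 135750 features per array, with array medians from 4.48 to 4.53, and 33616 named genes were tested, of which 17576 are protein-coding. Nothing in the labels says that the arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical, and the number of arrays limits the precision.

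The comparison asked how expression differs between cells with different levels of apoM. APOM was far higher in the overexpression group, at a log2 value of 15.63 ± 0.19 (SD, n = 3) against 5.88 ± 0.51 (SD, n = 3) in NC. The log2 change was 9.76 with a standard error of 0.25, an 865-fold difference (limma, adjusted p = 1.34e-07). Signal over background was not analysed here and the NC level lay at the 58.2 percentile of genes tested, so that this fold may understate the difference. All 3 overexpression arrays lay above all 3 NC arrays. An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest p that 3 arrays against 3 can give. The next largest rise of a protein-coding gene was 2.07, for SNRPD2.

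**Figure D1:**
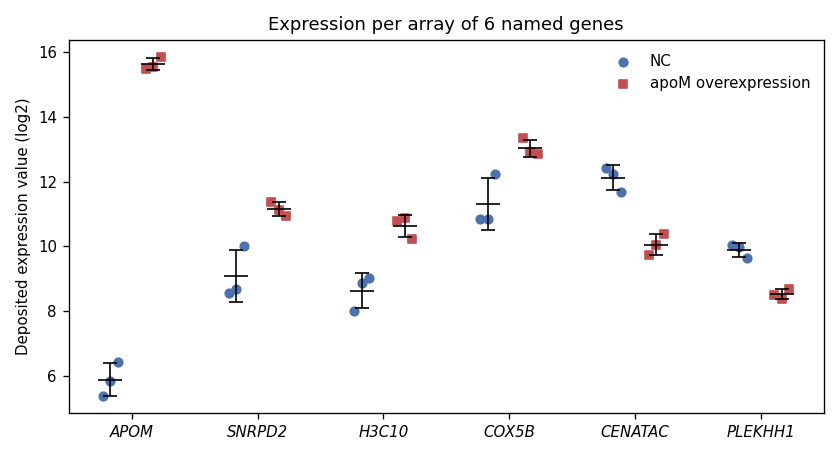
Deposited log2 expression of 6 named genes on each array, with NC arrays as circles and apoM overexpression arrays as squares; black lines mark the group mean and SD (n = 3). APOM moved from a mean of 5.88 to 15.63, and the other genes differed by 2.07 or less.

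Beyond APOM, protein-coding genes past the threshold changed by 2.07 or less on the log2 scale. Histone genes, SNRPD2, FAU and COX5B were higher in the overexpression group, while genes of the NPIP family, CENATAC, GOLGA8B and PLEKHH1 were lower. In all, 691 genes passed an adjusted p of 0.05 in limma, with 571 higher and 120 lower, and 198 of them were protein-coding, 153 higher and 45 lower. The median change of all genes tested was 0.09. The arrays of the groups did not overlap in 24.4% of genes, where 10% is the mean share over all splits into 3 and 3. Genes vary together across the arrays, so a single split can lie far from 10%. The shares of the other splits were not analysed here. The count of 691 varied with the array left out. It was 2 without apoM overexpression replicate 1, 8 without NC replicate 2 and 17 without apoM overexpression replicate 2. It was 44 without NC replicate 1, 235 without apoM overexpression replicate 3 and 2358 without NC replicate 3. Each such fit has fewer arrays, so these counts cannot tell lost power from reliance on single arrays. Over these fits the change ran from 1.80 to 2.53 for SNRPD2 and 1.68 to 2.20 for H3C10. For CENATAC it ran from -2.28 to -1.91 and for NPIPB3 from -1.59 to -1.21. Of the 48 genes past the threshold that are named in the text, 48 still passed without NC replicate 3 and 21 without apoM overexpression replicate 3. Without NC replicate 1 there were 5, APOM, H3C10, CENATAC, RNA5SP242 and VTRNA1-3, and without NC replicate 2, apoM overexpression replicate 1 or apoM overexpression replicate 2 there were 2, APOM and RNA5SP242. Over all 135750 features, the same 2 passed, and 1986 features had a limma adjusted p under 0.1. On the first principal component, with 51.1% of the variance, NC replicate 3 lay at -7.11. It stood between NC replicates 1 and 2, at -59.6 and -39.0, and the apoM overexpression arrays, at 41.9, 39.6 and 24.3.

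Core histone genes, whose products form the nucleosome, made up 7 of the 12 largest rises of protein-coding genes. H3C10 rose 3.99-fold (SE 0.28 on the log2 scale, adjusted p = 0.0179). On the log2 scale H4C1 rose by 1.98 and H3C2 and H4C4 by 1.80 each. H2BC10 rose by 1.73, H2BC8 by 1.69 and H2BC11 by 1.66. SNRPD2, a core protein of spliceosomal snRNPs, rose from 9.08 ± 0.81 to 11.15 ± 0.22 (SD, n = 3; limma adjusted p = 0.0273). FAU, which encodes ribosomal protein eS30 fused to a ubiquitin-like protein, rose by 1.82 (SE 0.33). COX5B, a subunit of cytochrome c oxidase, rose by 1.73 (SE 0.35), and S100A13, a calcium-binding protein, by 1.72 (SE 0.28).

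Among the 12 largest falls, CENATAC, a protein of the minor spliceosome, fell by 2.07 (SE 0.23, adjusted p = 0.0109) on the brightest of its 11 features. That feature and 9 others carry no mapped position in their names, so that which transcript was read is uncertain. The mean of these features gave -0.83 (adjusted p = 0.0523), which ends the call; 10 of the 11 were lower, with changes from -2.07 to 0.09. GOLGA8B fell by 1.71 and PLEKHH1 by 1.37, with adjusted p-values of 0.0273 and 0.0138 in limma. Of the 14 NPIP genes tested, 8 fell and all 14 were lower, with a median change of -1.18. The falls included NPIPB3 by 1.38, NPIPB4 by 1.37, NPIPA5 by 1.33, NPIPB5 by 1.29, NPIPB11 by 1.27, NPIPA1 by 1.24 and NPIPB15 by 1.22. These genes are near-identical copies whose probes may read one another, so the values of single members are uncertain. RPL5 fell by 1.53 and PLGLB1 by 1.27, each on a feature to which the platform annotation gives no gene ID, so that which transcript was read is uncertain.

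Of 41 gene lists fixed beforehand, 6 passed in camera with its preset correlation of 0.01, all of them higher with apoM. Splits of the 6 arrays that mixed the groups passed up to 7 lists at this setting. A mixed split still holds unequal numbers of NC arrays on its sides, so part of any group difference stays in it. The number of lists passed thus neither sets the real groups apart nor counts against a group difference. Replication-dependent histones, which package newly made DNA, rose most: 31 of 46 measured genes rose, none fell, and the median change was 1.12 (adjusted p = 2.81e-28). H2AC15 rose by 1.37, H2AC12 by 1.19 and H2BC8 by 1.69. With an estimated correlation this list did not pass (adjusted p = 0.899 with an estimated correlation), nor in fry (adjusted p = 0.143). Adjusted over the list alone, 44 of its members passed. As deviations from each gene's mean, its medians on NC replicates 1, 2 and 3 were -0.91, -0.68 and -0.12. With apoM they were 0.71, 0.67 and 0.38, so NC replicate 3 stood apart from the other NC arrays. The median gene span of these histones was 0.488 kb against 26.1 kb over all protein-coding genes tested.

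Cytosolic ribosomal protein genes had a median change of 0.75 over 51 measured members (camera adjusted p = 1.26e-14, and adjusted p = 0.899 with an estimated correlation). Of these, 3 rose, 1 fell and 47 did not pass; 41 passed adjusted over the list alone. FAU rose by 1.82, RPL27 by 1.62 and RPL9 by 0.92, and RPL5 was the member that fell. As deviations from each gene's mean, the medians of this list on single arrays were -0.77, -0.37 and 0.0059 in NC replicates 1, 2 and 3 and 0.37, 0.44 and 0.23 with apoM, so NC replicate 3 stood nearer to the apoM arrays than to NC replicate 1. With quantile normalization RPL27 and RPL9 missed the threshold (adjusted p = 0.0550 and 0.0759), as did PSMD8 and PKM, named below (adjusted p = 0.0591 and 0.0704). Nuclear genes of the respiratory chain had a median change of 0.75 over 49 members, 8 of which rose (camera adjusted p = 3.11e-16, and adjusted p = 0.899 with an estimated correlation). Their medians on single arrays were -0.74, -0.44 and 0.02 in NC and 0.41, 0.48 and 0.20 with apoM. COX6A1 rose by 1.36, COX6B1 by 1.34, COX5B by 1.73 and ATP5MC3, a subunit of ATP synthase, by 1.02, and 36 members passed adjusted over the list alone. Mitochondrially encoded genes gave a median of -0.0017 over 8 members (camera adjusted p = 0.705), but 4 of them lay within 0.05 of the highest value of every array, where no change can be read. The other 4 had changes from -0.07 to 0.10, with COX2 also near the maximum. The member at -0.07 read 17.0277 on NC replicates 1 and 2 and on apoM overexpression replicate 3. It read 17.0252 on apoM overexpression replicates 1 and 2. These shared values moved with the array maximum, so this change may not be readable either. Proteasome genes had a median of 0.51, with 2 of 28 members past the threshold, PSMA3 at 1.19 and PSMD8 at 0.88 (camera adjusted p = 3.40e-07, and adjusted p = 0.899 with an estimated correlation), and 14 adjusted over the list alone. The proteasome medians on single arrays were -0.56, -0.27 and -0.02 in NC and 0.27, 0.34 and 0.17 with apoM. Median gene spans were 5.02 kb for the ribosomal proteins, 10.5 kb for the respiratory chain and 17.7 kb for the proteasome.

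Cholesterol synthesis genes passed as a list with a median of 0.34 over 20 members, although no single member did (camera adjusted p = 0.0287, and adjusted p = 0.899 with an estimated correlation). FDPS, which makes farnesyl diphosphate, had a change of 0.70 (SE 0.18), IDI1 of 0.65 and NSDHL and MVD of 0.61 each, and 5 members passed adjusted over the list alone. Genes of the G2/M phase gave a median of 0.28 over 30 members, with none past the threshold (camera adjusted p = 0.0367, and adjusted p = 0.938 with an estimated correlation). The G2/M medians on single arrays were -0.24, -0.22 and 0.06 in NC and 0.10, 0.15 and 0.10 with apoM. NC replicate 3 thus stood nearer to the apoM arrays than to the other NC arrays. CCNB1, the mitotic cyclin B1, had a change of 0.76 and BIRC5, the inhibitor of apoptosis survivin, of 0.74, and 5 members passed adjusted over the list alone. Neither list passed without NC replicate 1 (adjusted p = 0.0661 and 0.12) or without apoM overexpression replicate 2 (adjusted p = 0.135 and 0.123). Cholesterol synthesis also missed the threshold without NC replicate 3 (adjusted p = 0.0634) and apoM overexpression replicate 1 (adjusted p = 0.0508), and G2/M without NC replicate 2 (adjusted p = 0.145) and apoM overexpression replicate 3 (adjusted p = 0.0823). With quantile normalization the G2/M median was 0.15 (adjusted p = 0.714). With the trend on gene span removed over protein-coding genes, a version chosen after seeing the data, the medians were 0.15 for each list, and both passed in camera with its preset correlation (adjusted p = 0.0208 and 0.0135).

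**Figure D2:**
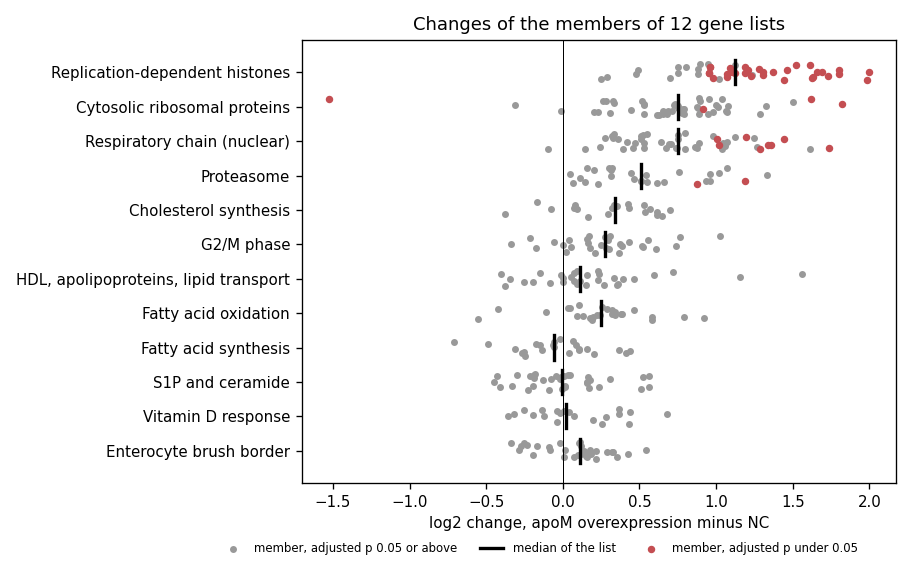
Change of each measured member of 12 gene lists on the log2 scale, apoM overexpression minus NC; red points passed adjusted p 0.05, grey points did not, and the black bar is the median of the list. The median was 1.12 for replication-dependent histones and 0.11 for the HDL, apolipoprotein and lipid transport list.

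In the lists nearest to the known role of apoM, no member passed over all genes tested in the main fit. With quantile normalization APOC1 passed (limma adjusted p = 0.0445) and APOA2 did not (limma adjusted p = 0.0711). With 1 array left out, the limma adjusted p ran from 0.0067 to 0.174 for APOC1 and from 0.0079 to 0.169 for APOA2. For APOC3 it ran from 0.0183 to 0.271, so the call of these genes depended on the array left out. The list of HDL, apolipoproteins and lipid transport gave a median of 0.11 over 31 members (camera adjusted p = 0.705). APOC1 had a change of 1.56 (SE 0.34, adjusted p = 0.0512) and APOA2 of 1.16 (SE 0.26, adjusted p = 0.0534), each with its groups apart, and both passed adjusted over the list alone. Passing in that way was not particular to this list. It held for 2 of 31 members here, 8 of 26 NRF2 targets and 6 of 32 spliceosome genes. APOC3 had a change of 0.72 and APOH of 0.60. Genes of sphingosine-1-phosphate and ceramide metabolism gave a median of -0.00797 and a mean of 0.00427 over 34 members (camera adjusted p = 0.263); SPHK1, a sphingosine kinase, had a change of 0.56 (adjusted p = 0.134), ASAH1 of 0.52, CERS3 of 0.51 and DEGS1 of -0.41. Fatty acid synthesis gave a median of -0.06 over 23 members (camera adjusted p = 0.236), with LPIN2 at -0.71, PLIN2 at 0.44, AGPAT2 at 0.41 and FADS2 at 0.36. Fatty acid oxidation gave 0.25 over 26 members (camera adjusted p = 0.153), with ETFB at 0.92, ECI1 at 0.79 and ETFA and ECI2 at 0.58 each. Bile acid genes of LXR and FXR gave 0.12 over 21 members (camera adjusted p = 0.971), with CYP7A1 and SLC51B at 0.34 each, CYP8B1 at 0.28 and ABCC2 at -0.25. Vitamin D response genes gave 0.02 over 20 members (camera adjusted p = 0.971). VDR, the vitamin D receptor, was at 9.97 ± 0.07 in NC and 10.33 ± 0.03 with apoM (SD, n = 3; limma adjusted p = 0.205), KLK6 had a change of 0.68 and S100G of 0.44. RPS27A was not analysed here.

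Lists of intestinal cell identity did not pass. Enterocyte brush border genes gave a median of 0.11 over 32 members, intestinal stem and WNT genes 0.01 over 24, goblet and secretory genes 0.11 over 22, enteroendocrine genes 0.15 over 21, and HNF transcription factors and targets 0.16 over 24, with camera adjusted p-values from 0.517 to 0.932. AGR2, a goblet cell protein, had a change of 1.27 (SE 0.30, adjusted p = 0.0596), and SERPINA1, the gene of alpha-1-antitrypsin, of 0.68 (adjusted p = 0.0548). Epithelial junction genes gave a median of -0.02 and a mean of 0.02 over 27 members (camera adjusted p = 0.397), and mesenchymal genes 0.15 over 28 (camera adjusted p = 0.717), with TAGLN at 1.04.

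Single members of 5 further lists passed without their list. TK1 and GINS2, both of DNA replication, rose by 1.08 and 1.34 in the S phase list, whose median was 0.17 over 29 members (camera adjusted p = 0.351). LCN2, the iron-binding lipocalin 2, rose by 0.81 in the NF-kB list, whose median was 0.02 over 27 (camera adjusted p = 0.397). VEGFA, a vascular growth factor, fell by 1.01 and PKM, a pyruvate kinase, rose by 0.78 in the hypoxia and glycolysis list, whose median was 0.08 over 32 (camera adjusted p = 0.903). STC2 fell by 0.89 in the list of the ATF4 amino acid response, whose median was 0.05 over 27 (camera adjusted p = 0.653). SNRPD2 was the member of the spliceosome list that rose; its median was 0.22 over 32 (camera adjusted p = 0.116).

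None of the other lists passed or had a member past the threshold over all genes tested. Adjusted over the list alone, 8 of 26 NRF2 targets, 5 of 28 apoptosis regulators and 5 of 30 xenobiotic metabolism genes passed. So did 2 of 29 immediate early genes and 1 of 24 ribosome biogenesis genes. Among the apoptosis regulators and the immediate early genes, the passing members went in both directions. Over all genes tested, 6437 of 33616 had an unadjusted p under 0.05 in limma. At that level were 12 of the 26 NRF2 targets, 10 of the 30 xenobiotic metabolism genes and 5 of the 28 apoptosis regulators. The medians of these lists were 0.23 for NRF2 targets, 0.23 for metallothioneins, 0.20 for heat shock genes, 0.20 for antigen presentation, 0.18 for ribosome biogenesis, 0.10 for apoptosis regulators, 0.08 for interferon response, 0.08 for ER stress, 0.06 for xenobiotic metabolism and 0.05 for p53 targets. With quantile normalization the ER stress median turned to -0.03. Of lists described above, hypoxia and glycolysis turned to -0.008, the ATF4 response to -0.01 and vitamin D response to -0.02. Immediate early genes had a median of 0.005 and a mean of -0.0455. Housekeeping genes gave 0.16, and 0.008 with quantile normalization. Among markers of other cell types, fibroblast genes gave 0.11, endothelial genes 0.08, erythroid genes 0.08 and leukocyte genes -0.08. Over the 35 lists that did not pass, camera adjusted p ran from 0.116 to 0.971. In 14 of them the median lay above 0 while the direction of the test, which sets a list against the other genes, was down. Mitochondrially encoded genes also differed in sign between median and mean.

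Change followed gene span. Among 8788 protein-coding genes above the median level, the change correlated with gene span at a Spearman rho of -0.41 across genes, which are not independent replicates. Spans come from the GRCh38.p14 gene table, include introns and are not transcript lengths. The median change was 1.07 over 71 genes under 1 kb, 33 of them histones of the list above, and 0.45 over the other 38. It was -0.17 in the bin of the longest genes. Protein-coding genes that rose had a median span of 5.51 kb and those that fell 28.2 kb, against 26.1 kb over all protein-coding genes tested, so the falls were of about the usual span. Slopes on span, per doubling, were taken on deviations from each gene's mean over the 6 arrays. They were 0.089, 0.045 and 0.0019 on NC replicates 1, 2 and 3, and -0.060, -0.051 and -0.025 on the apoM overexpression replicates (exact permutation p = 0.1, the smallest possible). Because of this centring, the mean slope of one group fixes that of the other. With this trend removed from the protein-coding genes, an alternative chosen after seeing the data, 301 genes passed, 123 higher and 178 lower, against 195 among protein-coding genes alone with the trend kept, 150 higher and 45 lower.

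**Figure D3:**
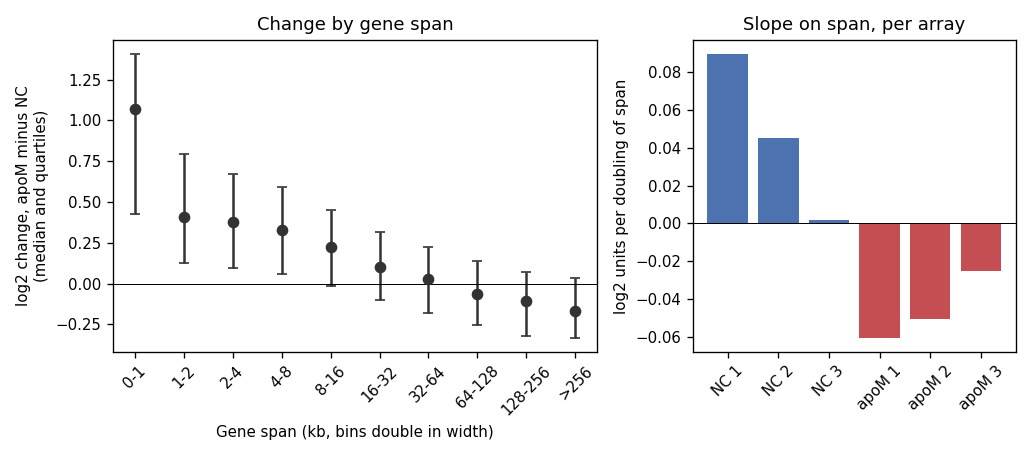
Left, median log2 change and quartiles of protein-coding genes above the median level, by gene span in kb; right, slope of each array's deviations on log2 gene span. The median change ran from 1.07 under 1 kb, or 0.45 over the 38 of these 71 genes outside the histone list, to -0.17 in the bin of the longest genes, and the slopes lay above 0 on the NC arrays and below 0 on the apoM overexpression arrays.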

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

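Alternatives restricted to protein-coding genes, to features with a gene ID or without the span trend were chosen after seeing the data. APOM passed in every alternative run on it, with log2 changes from 9.44 to 10.02 (9.51 to 10.02 with 1 array left out). The count of 691 genes was 1730 among genes above the median level, 1251 with trend and robust, 1679 with array weights, 3428 at an unadjusted p under 0.05 with a 1.5-fold change, 195 among protein-coding genes, 301 among protein-coding genes with the span trend removed, 357 with a gene ID and 2 over all features; the lower counts among protein-coding genes and with a gene ID come with fewer genes tested, and the cause of the others was not tested. With 1 array left out it ran from 2 (without apoM overexpression replicate 1) to 2358 (without NC replicate 3). The replicate block gave 50 genes and 4 lists; same-numbered arrays did not deviate together (highest correlation 0.033), and 2 of 6 arrays correlated best with their own number. The 6 lists became 0 with an estimated correlation, 0 in fry and 12 among protein-coding genes with the span trend removed (8 higher, 4 lower, the latter including the mitochondrially encoded genes at the array maximum), and 4 to 5 with 1 array left out. Cholesterol synthesis and G2/M each missed the threshold under the block (adjusted p = 0.0521) and among genes above the median level (adjusted p = 0.134 and 0.161), and G2/M with quantile normalization (adjusted p = 0.714) and the mean of a gene's features (adjusted p = 0.0561), over a range of 0.00705 to 0.899 and 0.00848 to 0.938 across alternatives. Over 88 named results, called or not and leaving out CYP7A1 and CYP8B1, 1058 of 1390 values kept direction and side of the threshold. Of the others 269 lost the call, 62 gained it and 1 reversed. The last was COX2, which lies near the array maximum and went to -0.62 with the span trend removed. Of the 48 called genes named, 2 to 48 stayed past the threshold with 1 array left out and 4 under the block; for the called lists 82 of 108 kept both and 26 lost the call. The count of 1730 among genes above the median level held 643 of the 691, so the count was lower with the dimmer genes kept. Signal over background was not analysed here, so how far genes without signal limit these counts is open.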

Other observations

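The small RNA classes, the families and the genes named in this paragraph were chosen after their values were seen. Small non-coding RNAs made up much of the count: 73 of 484 genes or pseudogenes of 5S rRNA rose and 0 fell, 65 of 249 snoRNA or scaRNA genes rose and 1 fell, and 137 of 1775 snRNA or snRNA-derived genes rose and 10 fell. RNA5SP242 rose by 2.39 (SE 0.18), SNORD3A, the U3 snoRNA of ribosomal RNA processing, by 1.70 (SE 0.22), SNORD17 by 1.78 and the vault RNA VTRNA1-3 by 2.55 (limma adjusted p = 0.0028, 0.0143, 0.0149 and 0.0127). Many of these genes have near-identical copies, so single members are uncertain. Of 1470 microRNA genes 2 rose and 17 fell, and of 3058 long non-coding RNAs 4 rose and 19 fell; the medians of these classes were -0.04 and 0.04. Besides NPIP, 4 of 12 AGAP, 2 of 6 ANKRD36, 2 of 21 NBPF and 1 of 12 GOLGA8 genes fell, with medians of -0.86, -0.68, -0.54 and -0.18, while 11 of 58 RPL7 pseudogenes rose, with a median of 0.71.

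All tests in the rest of this part were chosen after the result was seen, except those of the other splits of the arrays and of the APOM locus. Intervals are 95% bootstrap intervals over genes (2000 draws), which do not measure the spread between cultures. With 10 splits of the 6 arrays into 3 and 3, no share under 0.05 can be had. The real split gave 691 genes and the highest other split 0, so that 1 of the 10 splits gave as many. For gene lists the real split gave 6 and the highest other 7, and 3 of the 10 splits gave as many. The other splits hold unequal numbers of NC arrays on their sides. They thus keep part of any group difference, which also adds to the spread within their sides, and are not free of a group effect.

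The rise of APOM was set against a change of its whole locus. The 10 nearest measured protein-coding genes on each side, from BAG6 and C6orf47 outward, had a median change of 0.20 (0.08 to 0.35), the highest being 0.54 for CLIC1. Of these 20 genes 0 passed in limma and 5 had an unadjusted p under 0.05. This argues against a change of the locus. An introduced copy of APOM, which the group's name implies, stays open and was not tested, since no feature tells it from the gene's own transcript.

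The rise of histone, ribosomal protein, respiratory chain and proteasome genes was set against the trend with gene span. The 41 histone genes of the list under 1 kb, at any level, had a median change 0.74 above that of 38 other protein-coding genes under 1 kb and above the median level (0.39 to 0.93). With the 33 histones above that level the difference was 0.83 (0.48 to 1.07), and 0.86 (0.54 to 1.12) with 8 further histone genes and 4 mitochondrially encoded genes left out of the 38. Removing a span trend fitted without the histones of the list lowered their median from 1.12 to 0.63, and one fitted with them to 0.41. Only the same 38 genes under 1 kb supported the former, and 8 of these are further histone genes. That removal may thus take out part of a rise of histones itself. Those 38 were longer (median 0.744 kb against 0.486 kb), and the 7 of them within the quartiles of the histones' span were all histones, so for the histones a trend among the shortest genes and another cause cannot be told apart. For the other lists together the median went from 0.73 to 0.45 (0.39 to 0.56), and camera with its preset correlation kept each past its threshold; before the removal none of these lists passed with an estimated correlation (adjusted p = 0.899 with an estimated correlation). The fitted trend thus took up part of the rise of these other lists and not all of it. Whether the rest goes beyond a gradient shared by the arrays cannot be told. The intervals run over genes. Splits that mixed the groups passed up to 7 lists in camera at this setting, but they keep part of any group difference and cannot decide this. A response to apoM, growth state of the cultures and array processing may each account for the rest.

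The higher median of short genes and lower median of long genes were set against a gradient among the arrays that is unrelated to the groups and against a uniform loss of nuclear RNA. The slopes on span did not overlap between groups (exact permutation p = 0.1, the smallest possible), but they differed by 0.0876 within NC, nearly as much as the group means did (-0.091), so gradient and group cannot be told apart with 3 arrays against 3. An earlier form of this test was set aside: it correlated differences within a group with the change from the other arrays (r = 0.47, 0.63, 0.31, 0.29, 0.36 and 0.08), and 5 of 6 exceeded a cutoff of 0.1 that had been set after similar values were seen, with an orientation of the pairs that itself pushes r above 0. Against a uniform loss of nuclear RNA, 957 snRNA and snoRNA genes above the median level had a median change of 0.35 (0.30 to 0.40), and without that filter the medians were 0.17 for 1775 snRNA and 0.40 for 249 snoRNA genes; their rise was known when the test was chosen, so it could hardly have come out otherwise. A loss of long nuclear RNA alone was not tested. Of 11 genes picked after their values were seen, 5 fell and 6 did not pass. The falls were NKTR by 1.21, AGAP4 and MDM4 by 1.11, ANKRD36 by 1.08 and TRPM7 by 1.01. MALAT1 (-0.63), TUG1 (-0.65) and KCNQ1OT1 (-0.75) were among those that did not pass. Location in the cell was not measured for any of these 11, so they do not test a loss of long nuclear RNA.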
